A study of Mus musculus with 4 samples.

How the data were processed

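Total RNA from wild-type and Trim28 knockout mouse embryonic stem cells was converted to biotinylated cDNA from 250 ng per sample and hybridised to Affymetrix Mouse Gene ST arrays, per the labels' protocols. The protocol text names 24 h of 4-hydroxytamoxifen or vehicle and then 48 h of culture without it, for cells on irradiated embryonic fibroblasts. All 4 samples are labelled with 4-hydroxytamoxifen. Groups and replicate numbers came from the sample titles, which give 2 biological replicates per genotype. The deposited table holds log2 values made by the authors with affy and RMA, per the submitters' processing notes, which give no versions. RMA subtracts a modelled background, normalises arrays to each other and summarises probes, so that small differences among dim probe sets are compressed. Whether the version used here ran each of these steps with default settings is not given in the sources used here. The values were taken as deposited; they span 1.45 to 12.9, and the medians over all probe sets were 4.76 and 4.75 in the wild type and 4.76 and 4.77 in the knockout. Over the tested genes alone the medians differed by group, at 5.46 and 5.48 in the wild type and 5.66 and 5.63 in the knockout, so subtracting them moves every change down. No detection calls or background intensities were used here, so signal over background is unknown.

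The table has 35556 probe sets. A table of platform annotation lists 23099 of them, 21218 with 1 gene symbol and 1881 with several; the other 12457 are unnamed here. Of the 21218 single-gene probe sets, 21185 had a gene identifier found in the GRCm38.p6 annotation, and 0 symbols needed an update. That annotation served for names and for which genes neighbour each other, since the build behind the array annotation is not given in the sources used here. Only probe sets with 1 symbol were tested. For the 1386 genes with more than 1 such probe set, the one with the highest mean over all 4 samples was kept, which left 18820 genes. No filter on dim genes was applied.

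Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with 2 residual and 4.70 prior degrees of freedom and a prior SD of 0.105. All tests across genes were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; a second count asked for a change of at least 2-fold. The 20 gene lists were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the lists, and each was also counted with p-values adjusted over the list alone. The tests, the lists, the threshold, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Trim28, the 15 largest rises and 15 largest falls among genes past the threshold whose groups do not overlap, and up to 4 members of each list with the largest change among those past the threshold. It also names Pou5f1, Nanog, Sox2, Rnf2, Setdb1, Cdx2, Gata4, Gata6 and Pax6 whatever their values. Predicted genes and small RNAs among the largest changes were passed over, 1 among the rises (Gm5662) and 0 among the falls. Other genes named in the text were chosen after their values were seen.

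The fit was tested on simulated data for 18820 genes with the spread of the real arrays. It recovered 6 of 67 genes changed by 0.5 on the log2 scale (8.96%), 61 of 67 changed by 1 (91.0%) and 65 of 66 changed by 2 (98.5%), with 5 false calls. Of 100 lists drawn at random from all simulated genes, which could include changed genes, 2 had a camera p under 0.05. The simulated genes varied independently of each other, so this count does not bear on lists whose genes vary together. Changes near 0.5 were thus mostly missed in this simulation. Only the genes counted above were changed in it, far fewer than the 5071 called in the real data. The adjusted threshold was therefore stricter there, and its recovery does not give the recovery of the real comparison.

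The alternatives were the replicate number as a block, a prior with an intensity trend or robust to outlying variances, leaving out genes below the lower quartile or below the median of mean level, quantile normalization once more, subtraction of each array's median, the mean of a gene's probe sets, every single-gene probe set, each sample left out in turn, an adjusted p under 0.1, a fold limit of 1.5, camera with an estimated correlation and fry. Other background and normalization methods need scanner intensities and were not run. Leaving out the chromosomes with shifted stretches was added after seeing the data. These stretches were sought in blocks of 50 consecutive genes above the median level, against 1000 shuffles of the order of genes; the block size was also chosen after seeing the data, since a first run with 20 genes per block had a wider limit and did not call the chromosome 1 stretch. Permutation tests used 100000 resamples, and neighbouring genes were counted against 10000 shuffles within expression deciles. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.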

Results

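Transcript levels were measured in mouse embryonic stem cells, the self-renewing cells of the early embryo in culture, with and without Trim28. Trim28, also called KAP1 or TIF1-beta, is a co-repressor that KRAB zinc finger proteins bring to chromatin. The series title sets it beside the Polycomb protein Rnf2 and asks which differentiation genes and which pluripotency genes depend on it. Total RNA of 2 wild-type samples and 2 Trim28 knockout samples, labelled as biological replicates, was hybridised to Affymetrix Mouse Gene ST whole-transcript arrays, 1 array per sample. The cells grew on irradiated mouse embryonic fibroblasts, and no step to remove these feeder cells was given in the labels. The series design speaks of cells before and after conditional knockout. Yet all 4 samples are labelled with 4-hydroxytamoxifen, the inducer of the conditional deletion, and the wild-type samples with a wild-type genotype. Whether the wild-type cells were the same line before deletion or a separate line is therefore not settled by the sources used here. Values were log2 expression for 35556 probe sets, and 18820 genes were compared. Pearson's r over all probe sets, which are not independent replicates, was 0.994 between the wild-type arrays and 0.995 between the knockout arrays. Across the groups it lay between 0.974 and 0.976. With 2 arrays per group, the number of arrays limits the precision. The p-values set each change against the spread within both groups, moderated towards the spread of all genes. They do not cover variation between cell lines or clones. If the groups came from separate lines or clones, that difference cannot be told apart from loss of Trim28 for any gene.

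Trim28 itself, on chromosome 7 and the check of the labels, read 11.29 and 11.37 in the wild-type samples and 8.97 and 8.92 in the knockout samples (probe set 10550076). Its mean was 11.33 ± 0.06 in the wild type and 8.94 ± 0.03 in the knockout (SD, n = 2 each). The level fell by 2.38 on the log2 scale (SE 0.09, limma adjusted p = 3.39e-05), a 5.22-fold lower level (95% confidence interval of the knockout level, 16.5 to 22.3% of wild type). Which exons the probe set covers and which the deletion removes was not given in the sources used here, so the residual signal has no stated origin.

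The Trim28 knockout samples had large rises among interferon-response genes, fibroblast markers and 2-cell-stage genes and falls among pluripotency genes, compared with the wild type. None of these 4 lists passed with an estimated correlation between genes (adjusted p = 0.345, 0.235, 0.235 and 0.600). That correlation rests on 2 residual degrees of freedom, so missing the threshold there does not show that a list was unchanged. In the directional test of fry, which sets each list against no change, the adjusted p was 0.0174, 0.0209, 0.0105 and 0.0736. Among the genes compared, each read from probe sets listed with that gene alone, the largest rise was that of Gbp2, an interferon-inducible GTPase, from 3.47 ± 0.05 to 9.37 ± 0.01 (log2 5.90, SE 0.09, adjusted p = 2.22e-06). Alox15, a lipoxygenase, rose by 5.29 and Irgm1, another interferon-inducible GTPase, by 4.43. The contractile genes Acta2 and Tagln rose by 4.65 and 4.61. Pramel20 rose by 4.56, Cthrc1 by 4.33, the matrix gene Thbs1 by 4.22 and Pdlim3 by 4.12. The others of the 15 largest named rises were Tmem92 (4.05), Vnn1 (3.80), Pmp22 (3.74), Oasl2 (3.67), Fndc3c1 (3.62) and Tdpoz3 (3.61). The wild-type values of Gbp2, Pramel20 (2.52), Vnn1 (3.28), Tmem92 (3.38) and Tdpoz3 (3.42) lie at the low end of the array, where signal over background is not known, so the size and order of these rises hold for array values only. The wild-type samples differed in Acta2 (6.78 and 4.64) and Thbs1 (7.50 and 5.17), and with 1 sample left out at a time the rises ranged from 3.58 to 5.73 for Acta2 and from 3.06 to 5.38 for Thbs1.

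The deepest fall was that of Inhbb, which encodes an activin and inhibin subunit, from 8.51 ± 0.29 to 5.02 ± 0.34 (log2 -3.49, SE 0.19, adjusted p = 9.33e-05). Igsf21 (-3.24), the exchange factor gene Mcf2 (-3.18), the teneurin gene Tenm4 (-2.87) and Accsl (-2.81) followed. Further falls were those of Gpa33 (-2.64), Nr0b1 (-2.62), an orphan nuclear receptor of naive stem cells, the actin nucleator gene Cobl (-2.62), Dusp27 (-2.60) and Sh3rf2 (-2.52). Below these stood Trim28 itself, Septin1 (-2.34), Nkx6-3 (-2.33), the meiotic entry gene Stra8 (-2.28) and Hal (-2.26). Inhbb, Gpa33 and Dusp27 lie in a stretch of chromosome 1 whose genes were lower together in the knockout, described at the end.

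In all, 5071 of the 18820 genes (26.9%) passed an adjusted p of 0.05 in limma, 2676 higher and 2395 lower in the knockout. A change of at least 2-fold was found for 1109 of them, 835 higher and 274 lower, so that 75.3% were rises; 178 genes rose and 26 fell at least 4-fold. The genes at least 2-fold higher had a median wild-type level of 5.20 and those at least 2-fold lower one of 7.50. The balance depends on scaling. Over the tested genes the median change was -0.05 as deposited and after quantile normalization, and -0.22 with array medians subtracted. After quantile normalization 2499 genes were higher and 2855 lower, so that rises made up 46.7% of 5354 calls. The medians of the tested genes were 5.46 and 5.48 on the wild-type arrays and 5.66 and 5.63 on the knockout arrays; with each array's median subtracted, which moves every change by -0.17, rises made up 24.4% of 8457 calls (against 52.8%) and 57.6% of those of at least 2-fold. The count of calls was 2647 without wild-type replicate 1 and 2430 without wild-type replicate 2, and the count of lower genes was 1492 without knockout replicate 2.

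**Figure D1:**
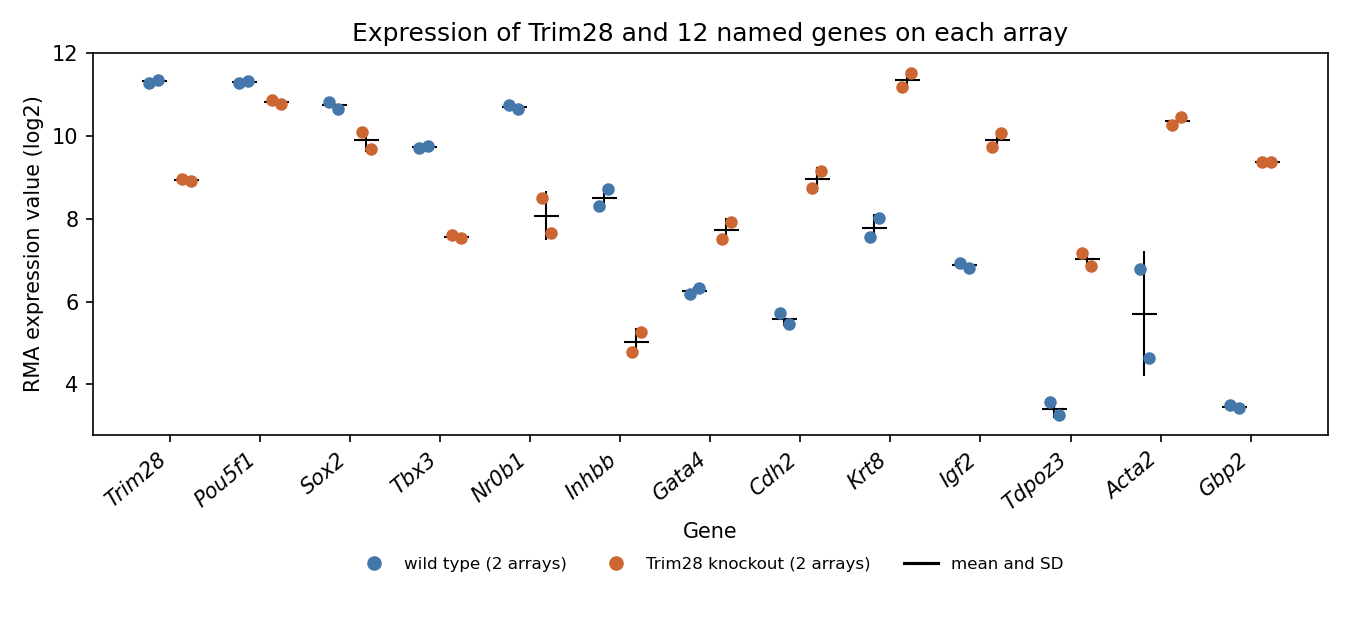
RMA expression values (log2, vertical axis) of Trim28 and 12 other named genes (horizontal axis) on the 2 wild-type and 2 knockout arrays; points are arrays, horizontal bars means and vertical bars SDs. Trim28 went from a mean of 11.33 to 8.94, Gbp2 from 3.47 to 9.37, and the wild-type values of Acta2 lay apart at 6.78 and 4.64.

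Genes of the pluripotency network were lower in the knockout. Of 38 measured members of the list fixed beforehand, 24 fell and 4 rose, 25 and 6 when adjusted over the list alone, with a median change of -0.55. The falls were deepest in Nr0b1 (-2.62), Tbx3 (-2.16), Tcl1 (-2.02) and Tet2 (-1.89); Tbx3 is a naive-state transcription factor and Tet2 a 5-methylcytosine dioxygenase. The core factors moved less, with falls in Sox2 (-0.85), Pou5f1 (-0.49), also called Oct4, and Nanog (-0.42). Nanog lies in a stretch of chromosome 6 whose genes were higher together. The 4 members that rose were Dppa3 (1.49), Lin28a (0.45) and the Nodal antagonists Lefty2 (1.17) and Lefty1. Dppa3 also lies in the chromosome 6 stretch. Of the 6 members in such shifted stretches, described at the end, 1 rose and 4 fell. On the chromosomes without these stretches, 1 of 28 members rose and 18 fell. The list was lower than other genes by camera (adjusted p = 1.99e-05), though not with an estimated correlation (adjusted p = 0.600). The directional test of fry, which sets the list against no change, gave an adjusted p of 0.0736. Leaving out wild-type replicate 1 or 2 raised the adjusted p to 0.0534 and 0.0683 for Pou5f1, 0.0689 and 0.176 for Nanog, 0.0771 and 0.0551 for Sox2 and 0.0561 and 0.0531 for Tcl1; Nanog also reached 0.141 without knockout replicate 2.

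Markers of the primed epiblast, the later stem cell state, were higher. Of 17 measured members 13 rose and 1 fell, 14 and 1 when adjusted over the list alone, and the median change was 1.02. Cdh2 (N-cadherin) rose from 5.59 ± 0.18 to 8.95 ± 0.30, a log2 change of 3.37 (adjusted p = 6.53e-05). Wnt8a rose by 2.20, the Wnt effector Lef1 by 2.08 and Zic2 by 1.94, while the stem cell factor gene Foxd3 fell by 1.66. The camera adjusted p was 5.42e-08, and with an estimated correlation adjusted p = 0.235. Fibroblast markers were higher in the same samples.

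Those fibroblast markers, which the feeder cells and contractile or mesenchymal cells share, formed the list with the lowest camera p (adjusted p = 1.51e-19, with an estimated correlation adjusted p = 0.235). Of 48 measured members 38 rose and 0 fell, both over all genes tested and adjusted over the list alone, with a median change of 1.05. Acta2 (4.65), Tagln (4.61), Thbs1 (4.22) and the myosin light chain gene Myl9 (3.33) rose most. The collagen genes Col1a1, Col1a2 and Col3a1 rose by 1.78, 1.23 and 0.49. Fn1, the fibronectin gene, read 10.88 in the wild type and 10.91 in the knockout.

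Trophoblast genes were higher as well, led by simple-epithelial keratins. Of 26 measured members 14 rose and 2 fell, 14 and 4 when adjusted over the list alone (median 0.77). Krt8 rose from 7.79 ± 0.32 to 11.36 ± 0.23 (log2 3.56, adjusted p = 6.79e-05), Krt18 by 3.36, Krt19 by 2.93 and the homeobox gene Rhox9 by 2.03. Cdx2, the trophectoderm factor, rose by 1.03, from 4.66 to 5.69. Its knockout level was near the medians of tested genes on the knockout arrays (5.66 and 5.63). Keratins are also made by other epithelia. The camera adjusted p was 5.32e-06, and with an estimated correlation adjusted p = 0.235.

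Among endoderm genes 15 of 30 rose and 3 fell, the same counts as when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 1.18e-04, with an estimated correlation adjusted p = 0.383). Plat (2.43), Srgn (1.94) and the basement membrane collagens Col4a2 (1.91) and Col4a1 (1.85) led. Gata4, a primitive endoderm factor in a stretch of chromosome 14 whose genes were higher together, rose by 1.47, and Gata6 had a change of 0.26 (adjusted p = 0.102). In the mesoderm list 13 of 35 rose and 0 fell, 14 and 0 when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 4.06e-04, with an estimated correlation adjusted p = 0.345). Wnt3 rose by 3.05, the VEGF receptor gene Flt1 by 1.87, Gata2 by 1.45 and Foxc1 by 1.36. Foxc1 read 3.40 in the wild type and 4.76 in the knockout, both below the array medians of tested genes. The mesoderm list shares 1 measured member with the fibroblast markers and the endoderm list shares 2. With array medians subtracted, the mesoderm counts were 9 and 6.

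Neural genes went both ways and did not pass (camera adjusted p = 0.170). Of 35 measured, 9 rose and 5 fell, 12 and 5 when adjusted over the list alone, and 7 and 8 with array medians subtracted. Nes (nestin) rose by 2.36 and the neurofilament genes Nefl and Nefm by 2.07 and 1.97, both of them in the chromosome 14 stretch, while the neurogenic factor Neurod1 fell by 1.49. Pax6 had a change of -0.01 (adjusted p = 0.956). Hox genes, which pattern the body axis, did not pass (camera adjusted p = 0.0680; 0.0316 without knockout replicate 1). Of 36 measured, 5 rose and 2 fell, also when adjusted over the list alone, and 2 rose and 4 fell with array medians subtracted. Hoxb1 rose by 1.06, from 4.30 to 5.36, both below the array medians of tested genes. Hoxb2 (0.57), Hoxb13 (-0.58) and Hoxb4 (0.50) lost their calls when single samples were left out.

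Genes of the 2-cell stage, the time of zygotic genome activation, were higher in the knockout. Of 44 listed, 22 were measured, and 18 of these rose and 0 fell, also when adjusted over the list alone, with a median change of 1.81. Tmem92 rose from 3.38 ± 0.24 to 7.43 ± 0.17 (log2 4.05, adjusted p = 3.04e-05). The predicted gene Gm5662 rose by 3.80, Tdpoz3 by 3.61 and Usp17la, of a family of ubiquitin proteases, by 3.40. The Tdpoz and Usp17l genes are near-identical copies whose probe sets cannot be assigned to single copies with certainty. The camera adjusted p was 1.29e-15, and with an estimated correlation adjusted p = 0.235.

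Imprinted genes, read from 1 parental allele, rose more often than they fell. Of 45 measured 20 rose and 5 fell, 21 and 6 when adjusted over the list alone (median 0.19); with array medians subtracted the counts were 18 and 9 and the median 0.02. Grb10, a growth inhibitor, rose from 5.77 ± 0.17 to 8.81 ± 0.13 (log2 3.04, adjusted p = 3.59e-05), the growth factor gene Igf2 by 3.03, Dcn by 2.64 and Nnat by 2.43. Dcn is also among the fibroblast markers. The camera adjusted p was 1.18e-04, and with an estimated correlation adjusted p = 0.235. Germline genes did not pass (camera adjusted p = 0.506). Of 50 measured, 4 rose and 11 fell, also when adjusted over the list alone (2 and 16 with array medians subtracted), and Stra8 (-2.28), Mael (-1.89), Piwil4 (-1.35) and Tex14 (-1.12) fell most. Mael lies in the chromosome 1 stretch.

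Interferon-response genes were higher, in part. Of 42 measured 22 rose and 4 fell, 22 and 5 when adjusted over the list alone and 22 and 9 with array medians subtracted (median 0.51, camera adjusted p = 1.33e-07, with an estimated correlation adjusted p = 0.345). The rises were led by Gbp2 (5.90), Oasl2 (3.67), Gbp3 (3.06) and the immunoproteasome gene Psmb8 (2.84). Among p53 targets and apoptosis genes 17 of 33 rose and 2 fell, also when adjusted over the list alone (median 0.47), and 14 and 5 with array medians subtracted. The leading members were Tap1 (2.36), a peptide transporter also in the interferon list, the death receptor gene Tnfrsf10b (1.90), Ddit4 (1.35) and Dcxr (1.35). Tnfrsf10b lies in the chromosome 14 stretch. The p53 list passed by camera (adjusted p = 1.04e-05) and missed the threshold with an estimated correlation (adjusted p = 0.516) and in fry's test against no change (adjusted p = 0.0736).

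Cell cycle genes were slightly lower, with 10 of 41 falling and 1 rising, also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0148, with an estimated correlation adjusted p = 0.600). The member that rose was Ccnd2 (1.89), a D-type cyclin gene, while Ccnd3 (-0.88), Nek2 (-0.69) and Bard1 (-0.63) fell; Bard1 had an adjusted p of 0.0730 without wild-type replicate 2. With array medians subtracted 24 fell and 1 rose. The call was lost after quantile normalization (adjusted p = 0.0966), without knockout replicate 2 (0.0982) and in fry's test against no change (0.0886). Of 33 hypoxia and glycolysis genes 10 rose and 3 fell, 11 and 3 when adjusted over the list alone (median 0.13, camera adjusted p = 0.0275, with an estimated correlation adjusted p = 0.692). Pfkfb3 (1.38), Ddit4 (1.35), Bhlhe40 (1.25) and Adm (1.09) led, of which Bhlhe40 lies in the chromosome 6 stretch and Pfkfb3 had an adjusted p of 0.0548 without wild-type replicate 1. This call was lost in 6 other alternatives, with an adjusted p of up to 0.479 without knockout replicate 1, and with array medians subtracted 6 rose and 5 fell, with a median of -0.04. Cholesterol synthesis genes did not pass (camera adjusted p = 0.295). Of 21 measured, 3 rose and 1 fell, 2 and 1 when adjusted over the list alone and 2 and 3 with array medians subtracted; Idi1 (0.66), Cyp51 (0.57), Pmvk (-0.51) and Fdft1 (0.34) passed over all genes, and each lost its call when at least 1 of the samples was left out.

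The chromatin lists did not pass as sets. Among Polycomb genes 6 of 35 rose and 11 fell, 7 and 11 when adjusted over the list alone (median -0.14, camera adjusted p = 0.332), and with array medians subtracted the counts were 3 and 20. Pcgf5 (0.89) and Yaf2 (0.74) rose, and Jarid2 (-0.73) and Eed (-0.67) fell; the adjusted p of Jarid2 was 0.101 without wild-type replicate 1 and 0.0813 without replicate 2. Rnf2 (Ring1b), the ubiquitin ligase of the complex named in the title, fell by 0.58 (adjusted p = 0.00560) and lies in the chromosome 1 stretch; its adjusted p was 0.0534 without wild-type replicate 1. Of 41 genes of the KAP1 complex and of H3K9 or DNA methylation 7 rose and 7 fell, 7 and 8 when adjusted over the list alone, and 4 and 16 with array medians subtracted. The median of that list was -0.08 and its camera direction was upward (adjusted p = 0.998), so the signs differ. Zmym2 (1.12, in the chromosome 14 stretch), Uhrf2 (0.85) and Pphln1 (0.59) rose. Zfp57 (-1.12), the zinc finger protein that guards imprints, fell. Setdb1, the H3K9 methyltransferase of the complex, had a change of -0.21 (adjusted p = 0.126; 0.0158 with array medians subtracted).

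Of 313 genes named Zfp plus a number, many of which encode KRAB zinc finger proteins, 40 rose and 46 fell, 42 and 48 when adjusted over the list alone (camera adjusted p = 0.720). The median was -0.02 and the mean 0.02. After quantile normalization 31 rose and 64 fell, and with array medians subtracted 29 rose and 95 fell. Zfp352 (2.36), Zfp608 (2.22), Zfp985 (1.82) and Zfp991 (1.38) had the largest changes. Among 18 reference genes 1 rose and 3 fell, also when adjusted over the list alone and with array medians subtracted (camera adjusted p = 0.848). B2m, which is interferon-inducible, rose by 0.65, while Tfrc (-0.48), Hprt (-0.44) and Tbp (-0.43) fell; each of the 4 lost its call when single samples were left out. In all, 12 of the 20 lists passed by camera, 10 higher and 2 lower. By fry, which sets a list against no change, 8 passed. With an estimated correlation, which rests on 2 residual degrees of freedom, 0 passed.

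**Figure D2:**
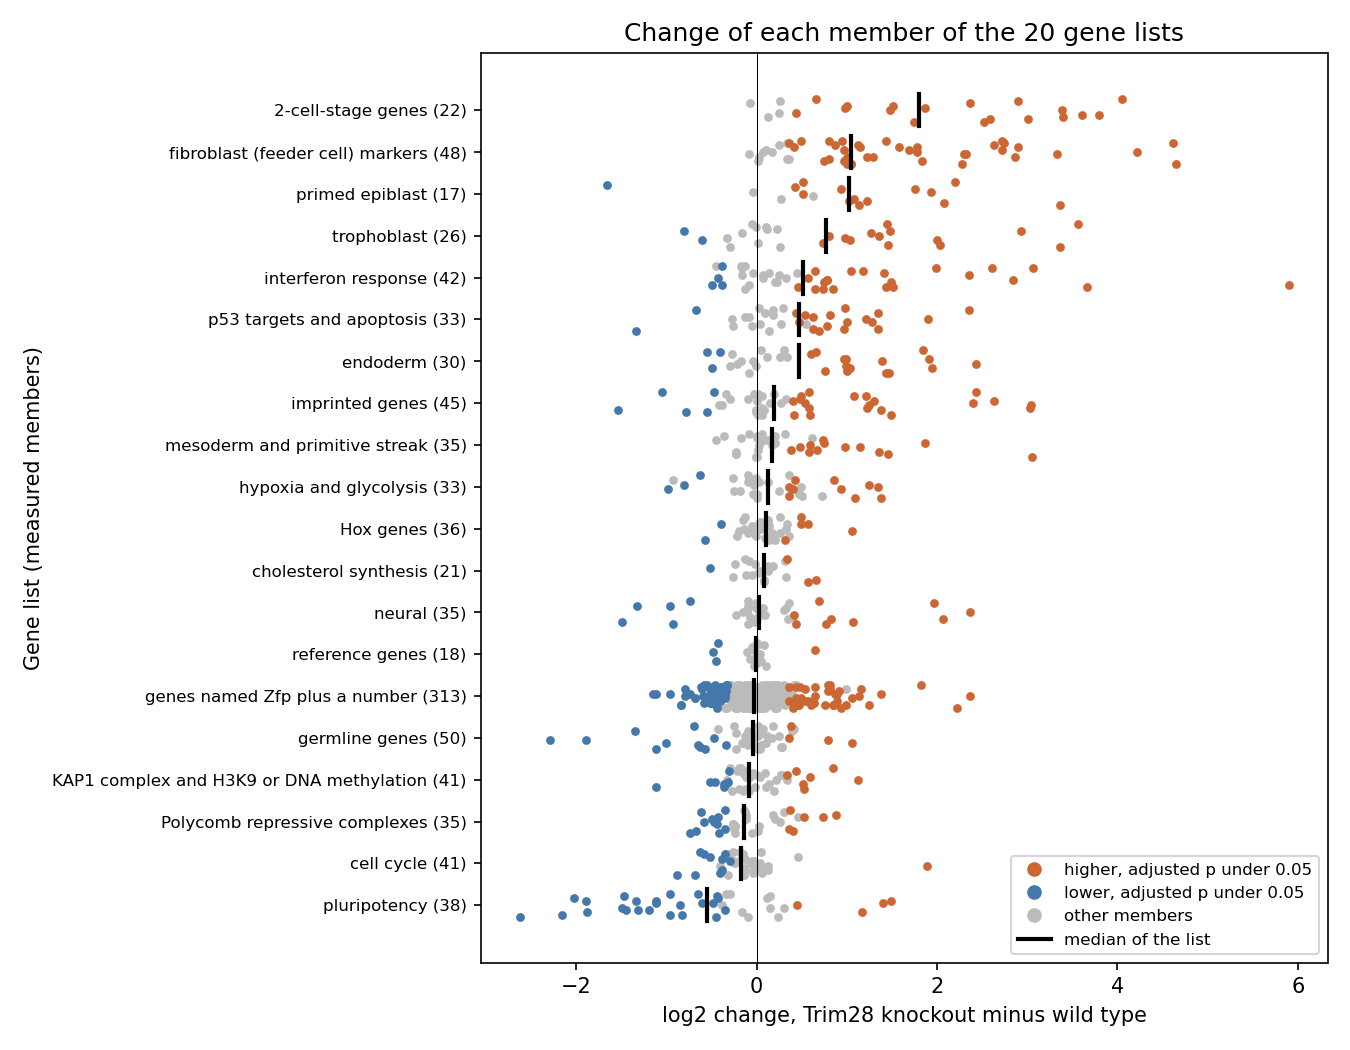
The log2 change of each measured member (points, horizontal axis, knockout minus wild type) of the 20 gene lists (vertical axis), with adjusted p under 0.05 in colour and the list median as a bar. The 2-cell-stage list has the highest median (1.81) and pluripotency the lowest (-0.55); with array medians subtracted the medians of the neural, Hox, hypoxia and cholesterol lists turn negative.

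Changes were also grouped along chromosomes, an arrangement examined after the values had been seen. Genes above the median level were placed in order by the GRCm38.p6 annotation, used only for neighbourhood, and taken in 179 blocks of 50 consecutive genes. On chromosome 1 the 300 genes from Tns1 to Coq8a had a median change of -0.44 ± 0.62 (SD over genes), and 82.0% of them lay below the median of all placed genes. On chromosome 14 the 150 genes from Fermt2 to Itm2b had a median of 0.54 ± 0.68, with 91.3% above it, and the next block, Med4 to Abcc4, one of -0.61. On chromosome 6 the 100 genes from Lsm3 to P3h3 had a median of 0.27 ± 0.48, with 83.0% above. In 1000 shuffles of gene order, the largest block shift of a shuffle exceeded 0.24 in 5% of cases. These 3 stretches of at least 2 blocks held 1186 tested genes: on chromosome 1, 49 were higher and 200 lower, on chromosome 6, 58 and 6, and on chromosome 14, 131 and 5. Of the genes named by the rule, Inhbb, Gpa33, Dusp27, Mael and Rnf2 lie in the chromosome 1 stretch and Nefl, Nefm, Zmym2, Tnfrsf10b, Fdft1 and Gata4 in that of chromosome 14. Bhlhe40 and Nanog lie in that of chromosome 6, as does Dppa3, named after its value was seen. Without chromosomes 1, 6 and 14, a setting chosen after seeing the data, 4156 genes passed, 2173 higher and 1983 lower, 894 of them by at least 2-fold, and 12 lists passed.

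**Figure D3:**
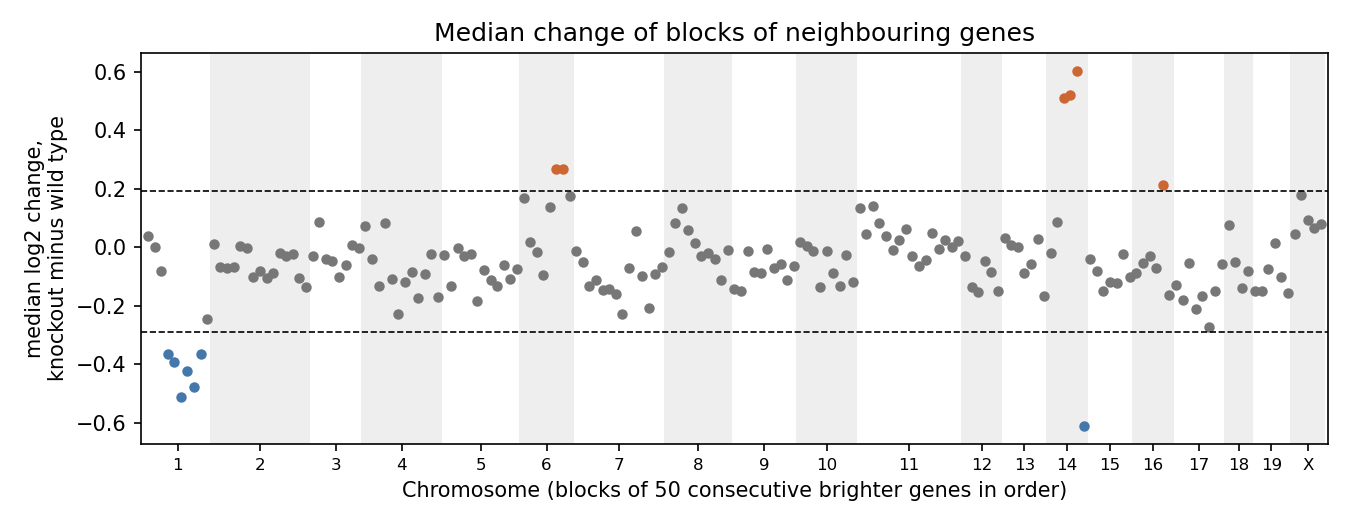
Median log2 change, knockout minus wild type (vertical axis), of 179 blocks of 50 neighbouring genes above the median level, in order along each chromosome (horizontal axis). Dashed lines mark the limits that 5% of shuffled gene orders pass; the coloured blocks beyond them on chromosomes 1, 6 and 14 form runs with medians of -0.44, 0.27 and 0.54, besides single blocks on chromosomes 14 and 16.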

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

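Of the tests below, those of stretches of neighbouring genes and of neighbours outside the shifted chromosomes were chosen after the results were seen, and the shares of rises with array medians subtracted and by each group's own level were added after the first results; the other tests were set before. Signal also changed in probe sets outside the gene comparison, which drew attention because nothing in the report uses them. Of the 12457 probe sets without a listed gene, 161 were at least 2-fold higher in the knockout and 74 at least 2-fold lower, with a largest rise of 5.75 on the log2 scale. Of the 1881 probe sets listed with several genes, 95 were at least 2-fold higher and 14 at least 2-fold lower, with a largest rise of 6.64.

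Fibroblast markers were higher in the knockout, and the cells shared their dishes with fibroblast feeder cells, so more feeder RNA in the knockout samples is a candidate explanation. Feeder RNA would raise 14 fibroblast-restricted matrix and surface genes at least as much as the other 34 members of the list; their median change was 0.89 against 1.14, a difference of -0.247 (two-sided permutation p = 0.368). Transcripts that are abundant in fibroblasts read, in the wild type and then the knockout, 5.88 and 7.66 for Col1a1, 5.07 and 6.30 for Col1a2, 4.59 and 5.08 for Col3a1, 10.03 and 11.47 for Vim, and 10.88 and 10.91 for Fn1. Only 2 of the 14 restricted genes, and 17 of all 48, lay above the median wild-type level of tested genes (5.47), so most sit low, where array values are compressed, and a small share of feeder RNA and expression by the knockout cells themselves cannot be told apart. The latter, the biological difference that the design names, was not tested separately.

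Stretches of chromosomes 1, 6 and 14 shifted as whole runs, and risen genes neighbour each other. A DNA copy number difference between the wild-type and knockout cells predicts that genes not used to choose a run shift with it. In runs chosen from every other gene, the 247 genes left out moved by a median of 0.373 in the run's direction. Of them 80.2% moved that way (exact binomial 95% interval 74.6 to 84.9%, too narrow because neighbouring genes on the same arrays are not independent). By run the median was -0.45 on chromosome 1, 0.55 on chromosome 14 and 0.27 on chromosome 6, where the bound of 0.3, set for the pooled genes, was not reached. The runs had been seen over all genes first and any regional shift would give this outcome, so a copy number difference and other regional changes cannot be told apart. For neighbours, 104 adjacent pairs were both at least 2-fold higher, against at most 65 in 10000 shuffles, and 22 pairs both at least 2-fold lower, against at most 14; 81 risen pairs without a shared name stem stood against at most 61, and 75 risen pairs outside chromosomes 1, 6 and 14 against at most 58 (one-sided permutation p = 1e-04 each, the smallest these shuffles can give). Outside those chromosomes 13 fallen pairs stood against at most 13 (one-sided permutation p = 6e-04). For the rises, these counts argue against chance placement. Taken singly, they also argue against paralogs with like symbols and against the shifted chromosomes as the whole cause. A stem here is the first 3 letters of a symbol, so paralogs with unlike symbols stay in the count. The stem and chromosome filters were not applied together, and what else groups the rises was not tested.

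Changes of at least 2-fold were mostly rises (75.3%), which array scaling or noise among dim genes may produce. Among genes above the median level, 550 rose and 233 fell, or 70.2% rises (exact binomial 95% interval 66.9 to 73.4%), above the bound of 60% set beforehand. But that level includes the knockout arrays, so a rise can carry a dim gene over it. The intervals given here count genes as independent although they share the same 4 arrays, so they are too narrow. The share was 58.9% (54.9 to 62.7%) above the median wild-type level, a choice that favours falls, 80.8% above the median knockout level, which favours rises, and 68.6% (64.5 to 72.5%) above both, so dim genes stay open as a contribution. After quantile normalization the share was 69.0% (66.2 to 71.8%), also above that bound, which argues against a scaling difference that quantile normalization removes as the whole cause. With array medians subtracted the share was 57.6% (54.6 to 60.6%), under the bound with an interval that reaches past it. Rises still outnumbered falls there, 624 to 459. That setting moved the median change over tested genes from -0.05 to -0.22, so it adds an offset towards falls. How much of the excess depends on scaling was thus not settled. A release of repressed genes by loss of Trim28, the biological difference in the design, and RNA from feeder cells stay open and were not tested for this share.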

How the results depend on the processing

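The fall of Trim28 stayed past the threshold in every alternative, between -2.55 and -2.34. Among named genes, excluding settings that leave out a sample, 1031 comparisons kept their direction and side of the threshold, 7 lost the call and 1 (Setdb1) gained it; with samples left out, 391 kept them, 39 lost the call and 2 reversed. With array medians subtracted, 8457 genes were called, 6392 of them lower and 459 at least 2-fold lower; by its construction that setting lowers every change, and the median over all genes moved by -0.17. The share of rises among calls was then 24.4%, against 52.8%. After quantile normalization that share was 46.7% of 5354 calls. Without the genes below the median level, 550 were at least 2-fold higher, as fewer genes were tested. A fold limit of 1.5 gave 2712 genes, 1744 higher and 968 lower. With an estimated correlation 0 lists passed, and by fry 8.

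With 1 sample left out at a time, where the lone sample is assumed to vary like the other group, 2430 to 4350 genes were called, 1531 to 2405 higher and 899 to 1945 lower; 1038 to 1280 changed at least 2-fold, 780 to 911 higher and 225 to 369 lower, and 11 to 12 lists passed. The fewest came without wild-type replicate 2 (2430) and replicate 1 (2647), and without knockout replicate 2 the lower genes numbered 1492. Both reversals were of Pax6, which ranged from -0.075 to 0.055 and turned positive without wild-type replicate 1 (0.005) and without knockout replicate 1 (0.055); the cause was not tested.

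Among lists, directions reversed in those far from the threshold; the cause was not tested. The KAP1 complex list turned downward with the replicate block (adjusted p = 0.992), without genes below the lower quartile (0.862) or the median (0.803), with the mean of probe sets (0.999), every probe set (0.559), without the shifted chromosomes, chosen after seeing the data (0.973), by fry (0.852), and without wild-type replicate 2 (0.732) or knockout replicate 1 (0.817), but not without the others (0.682 and 0.883). The neural and Zfp lists turned downward without genes below the median (0.528 and 0.803), and the Zfp list after quantile normalization (0.375) and, of the samples left out (0.506 to 0.954), only without knockout replicate 2 (0.954). The reference genes turned upward after quantile normalization (0.956), with every probe set (0.559) and, of the samples left out (0.682 to 0.949), only without wild-type replicate 2 (0.949).

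With the replicate number as a block 5093 genes were called, and the adjusted p of Nanog (0.0511), Fdft1 (0.0536) and Hprt (0.0602) passed over the threshold; deviations of same-numbered samples correlated at 0.145, and 2 pairs do not show that the numbers pair samples. Camera was not repeated for the trend and robust priors. The lack of signal over background limits all statements on dim genes.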

Other observations

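The tests on gene families, on imprinted genes by parent and on replicate numbers were chosen after the data were seen. Tested genes were grouped into 590 families of at least 5 symbols with a shared stem. By camera 4 families were higher and 0 lower. None of them passed with an estimated correlation (adjusted p = 0.943), which rests on 2 residual degrees of freedom. Guanylate-binding proteins (Gbp) came first, with 5 of 7 higher and a median of 1.90 (camera adjusted p = 3.39e-04). Gbp4 rose by 1.96 and Gbp7 by 1.90. Not all families of interferon-inducible genes rose: 3 of 5 Ifit, 1 of 14 Ifi, 0 of 9 Oas and 0 of 7 Ifitm genes were higher. Their medians were 0.74, 0.16, -0.16 and -0.17. In the Cdkn family, which holds the cyclin-dependent kinase inhibitors, 6 of 10 were higher (median 0.62, adjusted p = 0.00348), among them Cdkn2b (1.88), Cdkn1a (1.21) and Cdkn2a (0.76). Of 7 insulin-like growth factor binding proteins 4 were higher (median 0.47, adjusted p = 0.0347), with Igfbp3 at 3.07 and Igfbp4 at 2.82. Of 19 tetraspanins 9 were higher and 1 lower (median 0.25, adjusted p = 0.0141), led by Tspan2 (1.81) and Tspan14 (1.49). With array medians subtracted the medians of the Gbp, Cdkn, Igfbp and Tspan families were 1.73, 0.45, 0.30 and 0.08. Fibroblast markers rose in the same samples (38 of 48), and RNA of feeder cells, which also express Cdkn and Igfbp genes, was not separated from these rises.

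The microRNA genes Mir302b, Mir302c, Mir302d and Mir302a, which are neighbours on chromosome 3, rose by 1.96, 1.57, 1.62 and 1.45. Their wild-type levels lay at the low end of the array, between 2.39 and 2.97, and they were singled out after their values were seen. So were genes of the Y chromosome: the neighbours Uba1y and Kdm5d rose by 3.42 and 1.83, Uty fell by 0.47, and Eif2s3y had a change of -0.11 (adjusted p = 0.432).

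Imprinted genes are read from the maternal or the paternal copy, and Trim28 keeps imprints with Zfp57, which fell. If loss of imprinting favoured 1 parental class, paternally and maternally expressed genes would differ. The 22 paternally expressed genes had a median change of 0.30 and the 19 maternally expressed genes one of 0.27, a difference of 0.0247 (two-sided permutation p = 0.953). The test shows no difference at this size of list and does not show that the classes act alike.

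By replicate number, limma called 0 of 18820 genes, with 1212 at an unadjusted p under 0.05, which a share of 0.05 of unchanged genes passes by chance. The immediate-early genes Fos, Egr1 and Jun, taken from those with the lowest p-values, were lower in replicate 2 of both groups. They did not pass (limma adjusted p = 0.139, 0.139 and 0.226). Fos read 7.41 and 4.86 in the wild type and 8.89 and 5.51 in the knockout.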
